A study of Homo sapiens with 6 samples.

How the data were processed

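The measurements were NanoString panel values of total RNA from OVCAR-8 spheroids, in 3 control samples and 3 samples labelled DCLK1 knockout. Per the labels' protocols, spheroids formed for 48 h on poly-HEMA plates, and RNA was isolated with TRIzol and cleaned on a column kit. The panel, its probe sequences, the counting software and the normalisation are not given in the sources used here. Per the design text of the labels, transcripts under 20 counts in all samples were taken as not expressed, and genes with p under 0.05 and a fold beyond 2 either way were taken as changed.

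The deposited table held a normalised signal for 780 genes in 6 samples, with no value under 20. Each value other than 20 was a whole number times 1 factor per sample: 100% were whole within 0.011. The factors were 0.9087, 1.0287 and 1.1576 in control and 0.9161, 1.1182 and 1.0452 in knockout replicates 1 to 3. The recovered counts above the floor summed to 2069932, 1821489 and 1640603 in control and 2124498, 1671398 and 1730799 in knockout replicates 1 to 3. A value of exactly 20 was read as a floor, at which a gene has no known level, and 149 to 170 values per sample stood there. Genes at the floor in all 6 samples numbered 127 and were not tested; 653 were above it in at least 1 sample and 595 in all. The geometric mean of 20 genes that serve as references on such panels, a set chosen after the values were seen, was 1406.5 within 0.02 in 5 samples and 1412.7 in knockout replicate 1, the sample in which UBB stood at 20. From these values alone, the deposited scaling appears to rest on those genes.

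Because the signal values were not raw counts, the branch of the planned design for other units was used: limma 3.58.1 (lmFit, eBayes) in R 4.3.3 on log2(value + 1), with no further scaling, no covariates and Benjamini-Hochberg adjustment at 0.05 over 653 genes. Fold changes are on that scale, which understates the change of low genes, and more so near the floor. The median standard error was 0.085. The recovered counts were also tested with limma-voom, keeping the deposited scaling. In data simulated for this comparison over 653 genes, with 200 changed in each of 20 runs, 71.7% of changes of 0.5, 96.4% of changes of 1 and 99.8% of changes of 2 on the log2 scale were called, and 3.8% of calls were false. With 200 changed genes the threshold is laxer than with the 30 called here.

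Before the data were examined, 32 gene lists were fixed, of which 24 had at least 5 tested members. Each was tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the 24 lists, and its members were also adjusted over the list alone. The rule for named genes, fixed at the same time, took DCLK1, DCLK2, DCLK3 and DCX if measured, the 12 largest changes in each direction among called genes whose groups did not overlap (only 9 were higher), and up to 4 members with the lowest p from each list of at least 5. The 5 called genes outside the rule were FRMD6, IFNGR2, LRRC32, PLAU and SQLE. A few genes that the rule takes are not reported here by name, and they count in all totals. Gene names were matched to the RefSeq annotation of GRCh38.p14 for names only: 773 as symbols, 2 as synonyms, and 5 names of probes shared by several genes unmatched. No genome build is named for the panel, so no coordinates are given.

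Alternatives covered scaling, filters on low values, pseudocounts of 0.5 and 20, a mean-variance trend, another test per gene, the replicate number as a block and each sample left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.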

Results

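RNA was measured in spheroids of OVCAR-8, an established human cell line of high-grade serous ovarian cancer. Spheroids are cell clusters grown without attachment to a surface, here for 48 h on plates coated with poly-HEMA, which blocks adhesion. The line carries the label CPR, which the sources used here do not expand. A NanoString panel, in which barcoded probes hybridised to transcripts are counted directly, gave values for 780 genes in 3 control samples and 3 samples labelled DCLK1 knockout. The counts behind the values above a floor of 20 summed to between 1640603 and 2124498 per sample, and 653 genes lay above that floor in at least 1 sample. Because nothing in the labels says that the replicates were separate cultures, p-values measure only the spread between these samples, which may be technical.

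The single comparison of the design asked which panel genes differed when DCLK1, a doublecortin-like kinase, was knocked out. DCLK1 and its relatives DCLK2, DCLK3 and DCX were not measured among the genes analysed here, so the knockout itself could not be checked from these values. In the knockout samples the secreted protease inhibitor SLPI, the mucin MUC1, lactate dehydrogenase LDHA and the antiviral enzymes OAS1 and OAS2 were higher. The activin subunit INHBA, the ERK phosphatase DUSP6, the keratin KRT17 and the cytokines IL11 and IL6 were lower. Of the 653 genes, 30 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment (n = 3 per group), 9 higher and 21 lower, with folds from 1.23 to 2.94. At an unadjusted p under 0.05 there were 64 higher and 66 lower genes. The 3 knockout values lay outside the range of the 3 control values for all 30 genes, and for 27% of the 653, where chance gives 10%. The study's own threshold, an unadjusted p under 0.05 and a fold beyond 2, was passed by 4 genes, all lower: INHBA, DUSP6, KRT17 and TPSAB1/B2. Values rescaled to a list of reference genes gave 5 higher and 21 lower, while 7 genes passed with no filter on low values, which adds 127 genes of identical values to the test. With an equal-variance test on linear values, which does not share variance between genes as limma does, 4 genes passed. The count was 2 without control replicate 1, 5 without control replicate 2, 13 without control replicate 3, 4 without knockout replicate 2 and 5 without knockout replicate 3, and no called gene turned its direction.

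**Figure D1:**
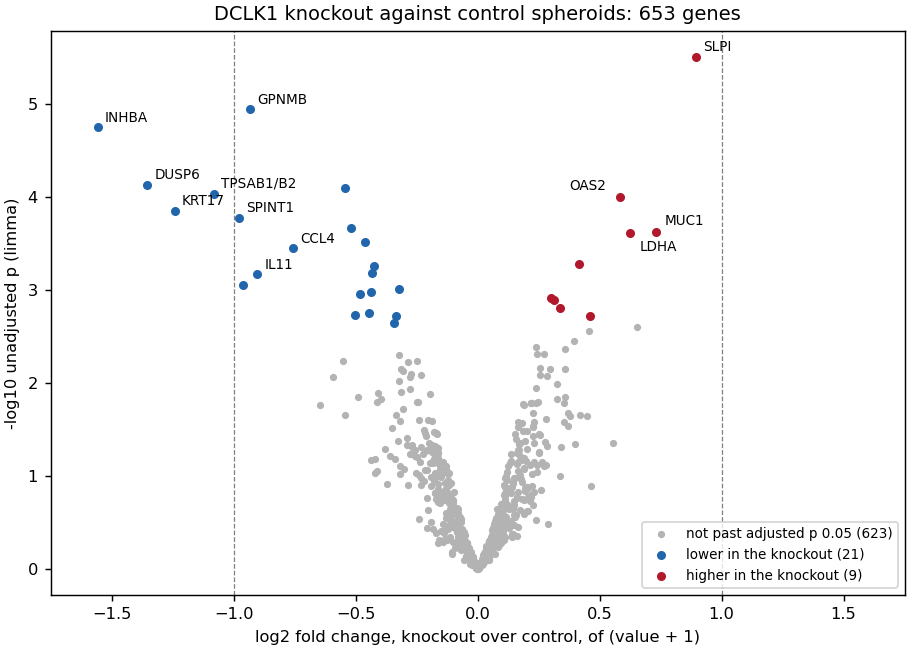
Log2 fold change (knockout over control, of value + 1; horizontal axis) against the -log10 unadjusted limma p (vertical axis) for 653 genes, with genes past an adjusted p of 0.05 in red where higher and in blue where lower. The 9 higher genes reach a fold of 1.86 (SLPI) and the 21 lower genes a fold of 2.94 (INHBA); dashed lines mark a fold of 2.

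INHBA showed the largest change of all, from 118 ± 12.3 in control to 39.9 ± 9.36 in knockout samples (SD, n = 3 each), and fell by 1.56 on the log2 scale (SE 0.16; limma adjusted p = 0.00386). DUSP6, which inactivates ERK kinases and is itself induced by ERK signalling, went from 274 ± 63.3 to 106 ± 16.5 and fell by 1.35 (SE 0.17, adjusted p = 0.00934). KRT17, an intermediate filament protein of basal epithelia, dropped from 13084 ± 2336 to 5554 ± 1101 (log2 fold change -1.24, SE 0.17, adjusted p = 0.0115). GPNMB, a transmembrane glycoprotein, went from 737 ± 64.7 to 385 ± 27.1 (log2 fold change -0.93, adjusted p = 0.00372). SPINT1, a membrane-bound inhibitor of serine proteases, went from 101 ± 9.34 to 51.5 ± 9.85 (-0.98, adjusted p = 0.0121). The tryptase probe TPSAB1/B2, named for more than 1 gene, whose transcripts cannot be told apart here, went from 66.6 ± 10.3 to 30.9 ± 4.94 (-1.08, adjusted p = 0.00934). The chemokine CCL4 fell by 0.76, PLA2G4A, which releases arachidonic acid from membranes, by 0.54, and the actin-associated PDLIM5 by 0.52, with adjusted p of 0.0165, 0.00934 and 0.0132. KRT17 and CCL4 have near-identical copies in the genome, and probe sequences were not used here to separate them. With single samples left out, the adjusted p rose to 0.0884 for INHBA, 0.0931 for DUSP6 and 0.11 for KRT17, TPSAB1/B2 and SPINT1, each without control replicate 2, while GPNMB stayed at or under 0.0427. It rose to 0.102 for CCL4 without control replicate 1, to 0.0817 for PLA2G4A without knockout replicate 2 and to 0.104 for PDLIM5 without control replicate 2. In these fits the log2 fold change stayed between -1.735 and -1.424 for INHBA, -1.477 and -1.171 for DUSP6, and -1.375 and -1.083 for KRT17. Here and below, a fit with fewer samples raises the adjusted p of most called genes, and the adjustment gives several genes the same value. Such a rise does not show that a gene rests on 1 sample.

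SLPI, an inhibitor of neutrophil elastase, rose from 1941 ± 117 in control to 3609 ± 132 in knockout samples, a log2 fold change of 0.90 (SE 0.07, limma adjusted p = 0.00203), the lowest p of all genes. MUC1, a membrane mucin of epithelial surfaces, rose from 189 ± 25.03 to 312 ± 24.2 (0.73, adjusted p = 0.0132). LDHA, which converts pyruvate to lactate, rose from 42486 ± 1776 to 65819 ± 7554 (0.63, adjusted p = 0.0132). STING1, the adaptor of cytosolic DNA sensing, rose by 0.34 (SE 0.07, adjusted p = 0.0402), and WWC1, a scaffold upstream of the Hippo kinases, by 0.46 (SE 0.10, adjusted p = 0.0428). With other scalings, WWC1 lost its call under all 4 tried (adjusted p up to 0.0631). STING1 lost it under that to the reference gene list (0.0581), a list that holds the called gene LDHA. With single samples left out, SLPI stayed at or under 0.0316, while the adjusted p reached 0.11 for MUC1 and LDHA and 0.188 for WWC1 without control replicate 2, and 0.156 for STING1 without knockout replicate 2.

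**Figure D2:**
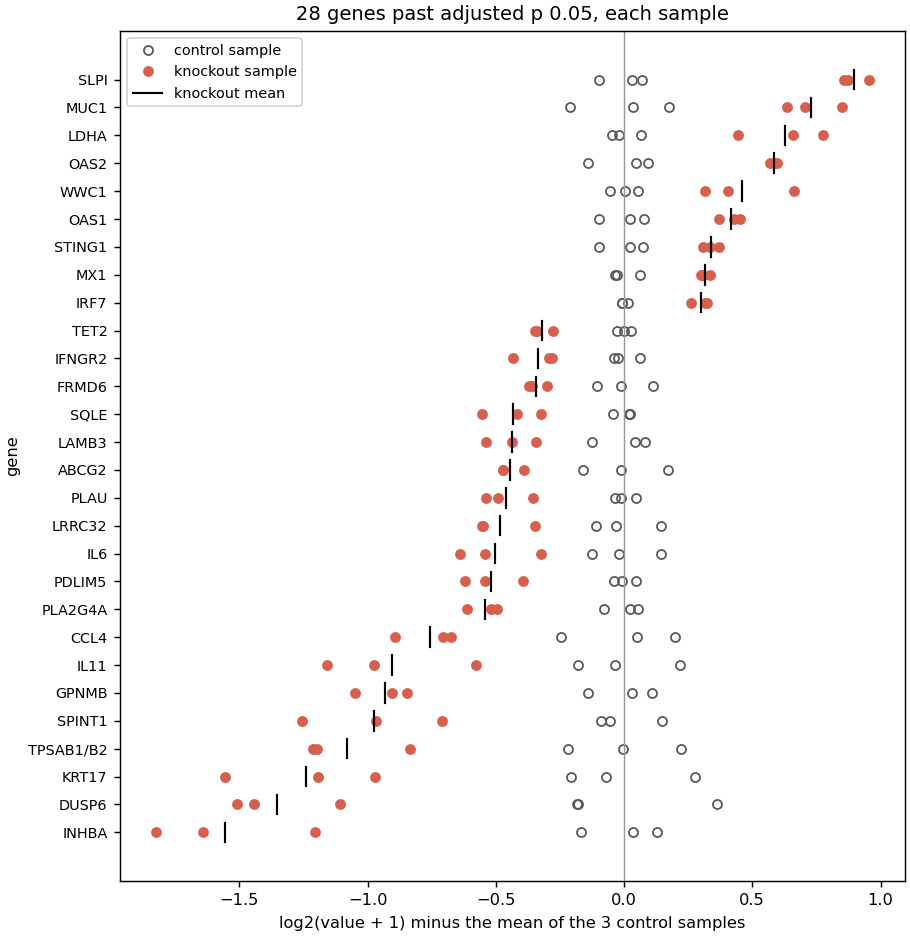
Values of each sample for 28 of the 30 genes past an adjusted p of 0.05, as log2(value + 1) minus the mean of the 3 control samples (horizontal axis), with open circles for control samples, filled circles for knockout samples and a bar for the knockout mean. In each gene the 3 knockout samples lie on 1 side of the 3 control samples.

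Interferon response and antigen presentation genes lay mostly above control in the knockout samples: of 25 tested members, 20 had a positive and 5 a negative log2 fold change, with a median of 0.17. OAS2, which makes the activator of RNase L, rose from 3913 ± 325 to 5853 ± 56.0 (log2 fold change 0.58, SE 0.08, limma adjusted p = 0.00934). OAS1, of the same enzyme family, rose by 0.42, the antiviral GTPase MX1 by 0.31 and the transcription factor IRF7 by 0.30, with adjusted p of 0.0222, 0.0347 and 0.0347. IFNGR2, a chain of the interferon gamma receptor, which was chosen after its values were seen, fell by 0.34 (adjusted p = 0.0428). Thus 4 members rose and 1 fell over all genes, and 6 rose and 1 fell when adjusted over the list alone. CXCL10 and CXCL11, interferon-induced chemokines also chosen after their values were seen, had log2 fold changes of -0.54 and -0.65 (adjusted p of 0.178 and 0.151). Of the myeloid markers, all 5 had positive log2 fold changes, with a median of 0.16, 1 at an unadjusted p under 0.05 and 0 called by limma or limma-voom. Among them, ITGAM lay above the floor in only 1 sample and CSF1R in only 3, so their signs carry little weight. The interferon list differed from the other genes with camera at a preset correlation of 0.01 (adjusted p = 0.00555 over 24 lists). The call was lost with an estimated correlation (adjusted p = 0.601) and without control replicate 2 (0.0771). Without the called members of every list, and with shorter lists also in the adjustment, its camera adjusted p was 0.15. Taking out members that passed weakens a list by construction. With single samples left out, the adjusted p of OAS2, OAS1, MX1 and IRF7 reached 0.0817, 0.113, 0.138 and 0.139, each without knockout replicate 2, and that of IFNGR2 0.143 without control replicate 3. Under other scalings MX1 lost its call with the reference gene list (0.052, at a log2 fold change of 0.29), and IRF7 lost it with 2 of 4 (up to 0.0608, at 0.26).

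The TGF-beta and BMP list, on signalling by these growth factors, lay below control: 9 of 10 tested members had a negative log2 fold change, with a median of -0.17. INHBA was the 1 member past the test over all genes, and 5 were lower when adjusted over the list alone. TGFB2, a ligand of the pathway, had a log2 fold change of -0.59 (SE 0.17, limma adjusted p = 0.108) and its receptor TGFBR2 -0.30 (SE 0.08, adjusted p = 0.105). The list passed camera at the preset correlation (adjusted p = 0.0416), but had an adjusted p = 0.601 with an estimated correlation. It also lost its call under scalings to the reference gene list (0.0582) and to the panel's reference genes without UBB and TFRC (0.0552), with no filter on low values (0.0639), without control replicate 1 (0.06) or 2 (0.125) and without knockout replicate 2 (0.121). Without INHBA its camera adjusted p was 0.15, with called genes taken out of every list and shorter lists also in the adjustment. Taking out a member that passed weakens a list by construction. With an estimated correlation, 0 of the 24 lists had an unadjusted p under 0.05. In fry, which tests whether members move on balance in 1 direction, 8 lists had an unadjusted p under 0.05 and 0 passed after adjustment (lowest adjusted p = 0.0588). In its test for change in either direction 16 passed, among them the list of reference genes (adjusted p = 0.00163), so that test did not set pathway lists apart from it.

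The mesenchymal, protease and matrix genes that passed were lower. PLAU, which encodes urokinase and was chosen after its values were seen, went from 6120 ± 180 to 4452 ± 301 and fell by 0.46 on the log2 scale (SE 0.07, limma adjusted p = 0.0154). Of 3 matrix proteases and inhibitors, 2 were lower, also when adjusted over the list alone. In the list of EMT transcription factors and mesenchymal genes 1 of 7 tested members was lower, over all genes and adjusted over the list alone, and all 7 had a negative log2 fold change (median -0.15, camera adjusted p = 0.102), among them ZEB1 at -0.18 and LOX at -0.34. LAMB3, a laminin chain, fell by 0.44 (adjusted p = 0.033) and was the 1 called gene of 13 in the extracellular matrix list, by either adjustment but not by limma-voom (camera adjusted p = 0.344). Of 8 integrins, the cell receptors for matrix, limma called 0 over all genes, with 1 higher and 5 lower at an unadjusted p under 0.05 and ITGAV called by limma-voom, and 4 lower when adjusted over the list alone. ITGAV had a log2 fold change of -0.32 (adjusted p = 0.0858) and ITGB1 -0.25 (adjusted p = 0.0943), and the list had a camera adjusted p of 0.102. MUC1 was the 1 called member of 7 epithelial adhesion genes by either adjustment (camera adjusted p = 0.199), and the adhesion receptor CDH1 lay at the floor in 5 samples. With single samples left out, the adjusted p of PLAU reached 0.104 without control replicate 2, and that of LAMB3 0.136 without control replicate 1.

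Inflammatory and cytokine genes gave a few lower members. IL11, a cytokine signalling through gp130, went from 313 ± 44.3 to 168 ± 35.7 and fell by 0.90 on the log2 scale (SE 0.16, limma adjusted p = 0.0246). IL6, which signals through the same receptor chain, went from 858 ± 81.5 to 606 ± 69.6 and fell by 0.50 (SE 0.11, adjusted p = 0.0428), but missed the threshold under 2 of 4 other scalings (adjusted p up to 0.0751). They were the 2 called members of 19 JAK-STAT genes, where 1 was higher and 2 were lower when adjusted over the list alone (camera adjusted p = 0.826). IL6 was also the 1 called member of 16 NF-kB and inflammatory cytokine genes by either adjustment, of which 12 were negative (median -0.20, camera adjusted p = 0.163), such as the adhesion molecule ICAM1 at -0.41 and the NF-kB inhibitor TNFAIP3 at -0.29. DUSP6 was the 1 called member of 19 MAPK and ERK targets, with 1 higher and 1 lower when adjusted over the list alone. In that list the median was 0.01, the mean -0.04, and camera pointed up and fry down (camera adjusted p = 0.954). With single samples left out, the adjusted p of IL11 reached 0.154 without control replicate 1 and that of IL6 0.185 without knockout replicate 3.

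Lists tied to drug response and metabolism each held at most 1 called gene. ABCG2, a drug efflux pump, went from 112 ± 13.2 to 82.1 ± 2.72 and fell by 0.44 on the log2 scale (SE 0.09, limma adjusted p = 0.0428), though its adjusted p reached 0.187 without knockout replicate 2 and limma-voom did not call it. It was the 1 called gene of 9 stemness genes by either adjustment, of which 8 were negative (median -0.32, camera adjusted p = 0.102), with MYC at -0.32 and the aldehyde dehydrogenase ALDH1A3 at -0.32. Among 11 drug transport and detoxification genes it was again the 1 called, with 1 higher and 1 lower when adjusted over the list alone. HMOX1, which breaks down heme, had a log2 fold change of 0.27 there (adjusted p = 0.0858; camera adjusted p = 0.461), and was the 1 gene of that list that limma-voom called. LDHA was the 1 called gene of 23 in the hypoxia, glycolysis and angiogenesis list by either adjustment, although 18 members were negative (median -0.13, camera adjusted p = 0.251) and the oxygen-responsive factor HIF1A stood at -0.28 (adjusted p = 0.0943). In the apoptosis list 1 of 12 genes was lower by either adjustment (camera adjusted p = 0.644), and the survival factor BCL2L1 had a log2 fold change of 0.19 (adjusted p = 0.215). TET2, which oxidises methylated cytosine, fell by 0.32 (adjusted p = 0.0316, reaching 0.138 without knockout replicate 2) as the 1 called gene of 19 chromatin modifiers by either adjustment (camera adjusted p = 0.461).

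Proliferation and repair genes gave no call over all genes in limma. Among 38 cell cycle genes, 1 had an unadjusted p under 0.05, the mitotic kinase PLK1 at a log2 fold change of 0.28 (adjusted p = 0.187), and 0 passed when adjusted over the list alone or by limma-voom. Among 25 DNA damage repair genes, 2 had such a p, FANCD2 at 0.23 and BRCA1 at 0.19, with 0 when adjusted over the list alone or by limma-voom. The 7 p53 targets, among them the cell cycle inhibitor CDKN1A at 0.16, gave 0 by each of these counts. At an unadjusted p under 0.05 there were 2 higher and 2 lower of 18 PI3K-AKT-mTOR genes, and 1 higher and 2 lower of 11 Wnt genes, among the lower ones the translation repressor EIF4EBP1 at -0.33 and the Wnt effector CTNNB1 at -0.22, with 0 when adjusted over the list alone or by limma-voom in either list. Of 15 receptor tyrosine kinases and ligands, 4 were higher and 1 lower at an unadjusted p under 0.05 and 0 were called by limma-voom, but 2 were higher when adjusted over the list alone: the growth factor receptors ERBB2 at 0.36 and PDGFRB at 0.40 (adjusted p of 0.0809 and 0.07 over all genes). The camera adjusted p was 0.95 for the cell cycle, repair, p53 and PI3K lists, 0.613 for Wnt and 0.344 for the receptor list. Medians and means or tests differed in sign for the cell cycle list (median -0.015, mean 0.008, fry down), the repair list (median -0.005, mean -0.002, camera up), the PI3K list (median -0.008, mean -0.023, camera up) and the receptor list (median -0.014, mean 0.090).

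Markers of other cell types gave no call over all genes. The 10 tested T and NK cell markers gave 0 calls in limma, limma-voom, adjusted over the list alone and at an unadjusted p under 0.05 (median -0.10, camera adjusted p = 0.344), and the 5 myeloid markers 0 calls over all genes, adjusted over the list alone or by limma-voom, with CD14 at an unadjusted p of 0.0228 and a log2 fold change of 0.38 (list median 0.16, camera adjusted p = 0.163). Of these myeloid markers, ITGAM lay above the floor in only 1 sample and CSF1R in only 3. The leukocyte gene PTPRC lay at the floor in all 6 samples. Among 22 reference genes, LDHA was the 1 called by either adjustment (median 0.001, camera adjusted p = 0.519), while the transferrin receptor TFRC had a log2 fold change of -0.49 (adjusted p = 0.149). The 6 immediate stress response genes gave 0 calls over all genes in limma and limma-voom, 2 at an unadjusted p under 0.05, and 1 higher (FOS, at 0.35) and 1 lower (MYC) when adjusted over the list alone (median -0.004, mean 0.008, camera adjusted p = 0.95). Shorter lists were counted without a list test, and none held a gene called by limma or limma-voom over all genes, apart from the protease list. At an unadjusted p under 0.05 there were 2 of 4 Notch genes, 2 of 3 Hedgehog genes, 0 of 4 migration genes, 1 of 2 fibroblast markers, 0 of 2 endothelial markers and 2 of 2 B cell markers. Adjusted over the list alone, JAG1 (-0.55) of Notch was lower, SMO (0.25) of Hedgehog and PDGFRB of the fibroblast markers were higher, and of the B cell markers 1 was higher and CD22 (-0.29) lower, these shorter-list genes being named after their values were seen.

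**Figure D3:**
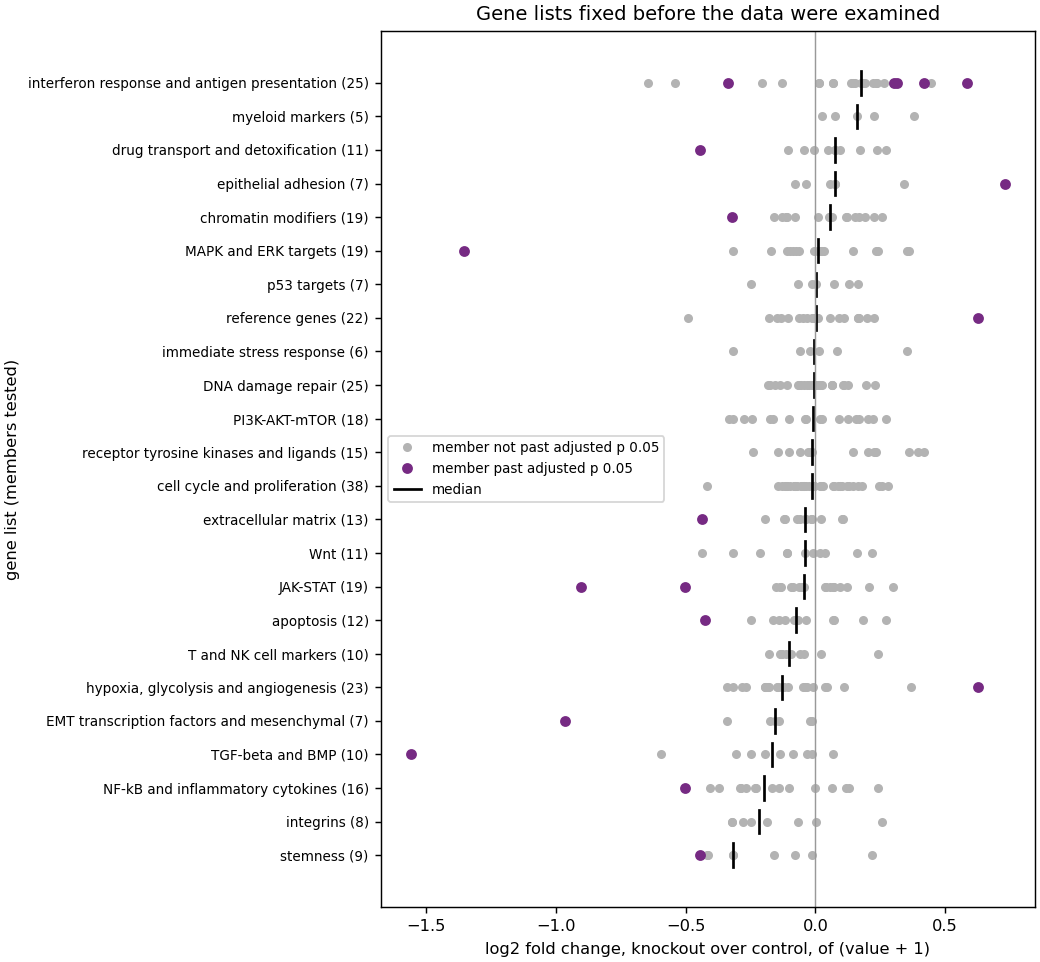
Log2 fold change (knockout over control, of value + 1; horizontal axis) of each tested member of the 24 fixed lists with at least 5 tested members, listed on the vertical axis with their sizes; purple points passed an adjusted p of 0.05 over all genes and bars are list medians. The interferon list has a median of 0.17 with 4 higher and 1 lower called members, and the TGF-beta and BMP list a median of -0.17 with INHBA called.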

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

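The scaling without UBB and TFRC, limma-voom, the filter to genes above the floor in all samples and the lists without called members were chosen after seeing the data. So were scalings, the mean filter, pseudocounts, the mean-variance trend and the floor of 20 for results they were not planned for. Of 25 named and called genes, 2 (SLPI and GPNMB) kept an adjusted p under 0.05 in all 19 alternatives run for single genes. Over all 95 named genes, 150 values lost the threshold, 16 gained it, 0 reversed after a call and 3 uncalled ones changed sign or became 0. The 30 called genes became 26 with reference gene scaling, 28 with median ratio and with TMM scaling, 30 without UBB and TFRC, 33 with a mean of at least 50, 31 with a mean-variance trend, 31 and 30 with pseudocounts of 20 and 0.5, 32 above the floor in all samples and 31 with limma-voom, of which 27 were shared. They became 7 with no filter, which adds 127 genes of identical values to the test, and 4 with an equal-variance test on linear values, where the cause was not tested. With single samples left out the count ranged from 2 to 21, with fewer samples in the fit. With a replicate block it was 27, of which 20 were shared. Deviations of samples with the same number correlated at 0.28, 0.02 and 0.27. The main fit held no block because the design planned no covariates, and an effect shared by replicate number is not excluded. On the first principal component (57.8% of the variance), replicates 1 to 3 stood at -3.91, -2.35 and -2.08 in control. In knockout they stood at 1.09, 2.47 and 4.8, the same order. The 4 genes past the study's threshold ranged from 3 to 6 over all alternatives, with 3 only under alternatives not planned for that count. The lists past camera numbered 2, and 1 with reference gene scaling, with no filter and without UBB and TFRC, 3 with a mean of at least 50, and 0 to 4 with single samples left out. For the interferon list the adjusted p was 0.15 without its called members and 5.14e-05 to 0.0771 with single samples left out. For the TGF-beta and BMP list it was 0.0582 with reference gene scaling, 0.0639 with no filter, 0.0552 without UBB and TFRC, 0.15 without INHBA and 0.0338 to 0.125 with single samples left out. Both values of 0.15 come from lists stripped of called members, which weakens a list by construction. The list used for reference gene scaling holds LDHA, itself called at 0.626, and had a mean log2 fold change of 0.027. That scaling moved the median of all genes from -0.0083 to -0.035, a shift close to the list's own mean. The scaling without UBB and TFRC leaves out TFRC, at -0.49, and moved the median to -0.046. Scaling to the list without LDHA was not run. A floor of 20 changed nothing, as the values already had it. Tests planned for raw counts, such as the edgeR quasi-likelihood test of the design, were not run, since the values are not raw counts. Genes near 20 are limited by the floor, so that a lower level there was not detectable.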

Other observations

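The tests on the interferon genes and on the low-abundance genes below, and the choice of the Hippo genes, were made only after the results were seen. For the interferon genes, a bound on the fold under other scalings replaced one on the adjusted p, and a median over leukocyte genes replaced first the marker medians and then the largest of those genes, each after the earlier value was seen. WWC1 and FRMD6, scaffold proteins upstream of the Hippo kinases, moved in opposite directions, with log2 fold changes of 0.46 and -0.34 (limma adjusted p of 0.0428 and 0.0488), although WWC1 lost its call under all 4 other scalings and both lost it when any 1 sample was left out. The other 9 of 11 Hippo pathway genes tested did not pass. The kinase LATS1 stood at -0.01, the coactivators YAP1 and WWTR1 at 0.02 and -0.08, the kinase STK4 at -0.24 and the angiomotin AMOTL2 at 0.29, and 1 of the 11 genes changed sign under each of 3 scalings and 0 under the median ratio. SQLE, an enzyme of cholesterol synthesis that was chosen after its values were seen, fell by 0.43 on the log2 scale (adjusted p = 0.0246), which reached 0.11 without control replicate 2. UBB, a ubiquitin gene among the genes on which the deposited scaling appears to rest, lay between 20 and 32.92 in the 6 samples, close to the floor.

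OAS1, OAS2, MX1 and IRF7 were higher in the knockout samples. A scaling error between samples that the 4 other scalings would correct is argued against as the whole cause. Over them the log2 fold changes were at least 0.38 (SE 0.07) for OAS1 and OAS2, which stayed past the threshold. They were at least 0.264 (SE 0.06) for MX1 and IRF7, which did not under every scaling. The factors of these scalings lay between 0.974 and 1.0255 per sample, close to the deposited scaling, so an error shared by all of them was not tested. With reference gene scaling MX1 went from 0.31 (SE 0.06) to 0.29 (SE 0.06, limma adjusted p = 0.052) and IRF7 from 0.30 (SE 0.06) to 0.27 (SE 0.06, adjusted p = 0.052). Without UBB and TFRC IRF7 went to 0.26 (SE 0.06, adjusted p = 0.0608), while MX1 kept its call at 0.277 (adjusted p = 0.0477). The folds were thus slightly smaller with a like error and the adjusted p lay close to the threshold on either side. The design as described holds only spheroids of OVCAR-8, a cancer cell line, and names no source of immune cells. From the values alone, RNA from immune cells in the knockout samples is not decided. The bound was replaced after earlier values were seen and compares signals of different probes. Of the 7 general leukocyte genes on the panel, PTPRC, ITGB2, ITGAL and IL2RG lay at the floor in all 6 samples. The largest rise that the values allow for the 7 genes had a median of 4.66% of the smallest gap between the groups among the 4 genes (429, for OAS1). It reached 16.1% for DOCK2 and 7.82% for CD53. DOCK2 went from 183 to 228 (log2 fold change 0.33, limma adjusted p = 0.122). The 5 myeloid markers had a median log2 fold change of 0.16, with CD14 going from 48.2 to 62.8, but ITGAM and CSF1R lay at the floor in some samples. A biological difference that goes with the knockout also stays open and untested.

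The low-abundance genes TPSAB1/B2, CCL4 and LRRC32 were lower in the knockout samples, and LRRC32 was chosen after its values were seen. A lower background shared by genes of that level is argued against, because all 71 genes with a mean from 30 to 100, called ones included, had a median log2 fold change of 0.079 (95% bootstrap interval -0.032 to 0.145, 2000 resamples). However, the 6 called genes among the 71 were all lower, these 3 with INHBA, SPINT1 and ABCG2. Of the 71, 14.1% lay under -0.4 against 4.2% over 0.4, but the 14.1% includes these 6 called genes and so partly restates the calls. A loss limited to some probes was not tested and stays open. Counting error alone was tested on the summed recovered counts with an exact conditional binomial test, and was argued against for TPSAB1/B2 and CCL4 (largest p = 3.15e-06), with 198 against 92 and 193 against 112 counts. For LRRC32, with 214 against 153 counts, the exact p of 0.00143 did not pass the bound of 0.001 set for it, so counting error stays open, as does hybridisation of these probes to other transcripts, which could not be tested; the genes were taken apart after that p was seen.

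Splits of the 6 samples into 3 and 3 number 10, too few for a share under 0.05. The real split gave 30 called genes and the highest other split 0, so 1 of the 10 splits gave as many. For the study's threshold the real split gave 4 genes and the highest other 0, again 1 of 10. For lists past camera the real split gave 2 and the other splits 2, 0, 1, 0, 1, 1, 0, 1 and 1, so 2 of 10 gave as many. Camera at the preset correlation thus also called lists in most splits that mix the groups.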
